A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

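Transcript levels were measured in Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a, on 4 Affymetrix expression arrays. Cultures had received honokiol, a biphenolic compound from magnolia bark, at 12 µg/mL for 2 h, or the same volume of its solvent ethanol. Groups and replicate numbers (2 arrays in each group) were taken from the sample titles, which call the replicates biological. The deposited table holds intensity values on a linear scale, 1 per probe set and array, made with RMA per the submitters' processing notes. RMA corrects the background, normalizes between arrays by quantiles and summarises the probes of a probe set. Its version is not given in the sources used here. The lowest intensity on an array lay between 2.58 and 2.77 and the highest between 21742 and 22549, so log2 was taken before any test, with no pseudocount. The plan made before the data were examined had taken the values to be on the log2 scale already; nothing else in it was altered. The number of arrays limits the precision, and RMA compresses fold changes of dim probe sets.

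Probe sets were named through the platform annotation and the gene table of S. cerevisiae assembly R64. Of 10928 probe sets, 5498 named 1 S. cerevisiae gene. Another 1747 named a gene absent from that table, as the array also carries probe sets for the fission yeast Schizosaccharomyces pombe, and 1 of these named several genes. The remaining 3683 had no gene name here, among them 166 AFFX and 47 RPTR control probe sets. The test covered 5449 genes, each through its probe set with the highest mean over the 4 arrays; 47 genes had more than 1 probe set. Of the tested probe sets, 113 carry a mark (s or x) that they can bind several transcripts, which matters for paralogs. No genome build was named with the values, so no coordinates are given. The background level was set at log2 intensity 4.39, the 95th percentile of the means of the probe sets for another species. For a gene with 1 group mean under this level, the fold is given as a bound, the brighter mean against the background level.

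Honokiol was compared with ethanol with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05. Errors of log2 fold changes are standard errors from this fit, which has 2 residual degrees of freedom and 2.76 prior degrees of freedom. All adjusted p-values for genes come from it. Before the data were examined, 36 gene lists were fixed from textbook knowledge, together with the list of genes deleted in BY4741, which was not tested. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 36 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run beside it. The 36 lists were those for Pdr1/Pdr3 drug resistance, Yap1 targets, iron, zinc, copper, phosphate, heat shock, general stress, trehalose and glycogen, the cell wall, ergosterol, hypoxia, fatty acids and phospholipids, respiration, the TCA cycle, the mitochondrial ribosome, glycolysis, gluconeogenesis, beta-oxidation, hexose transport, ribosomal proteins, ribosome biogenesis, Gcn4 targets, sulfate and methionine, thiamine and vitamin B6, the proteasome, the unfolded protein response, autophagy, the vacuolar ATPase, calcineurin, weak acids, DNA damage, G1/S, G2/M and M/G1, histones and mating.

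The genes named were fixed by rule: the 12 largest rises and the 12 largest falls among genes past the threshold whose honokiol arrays both lay on the same side of both controls and whose brighter group mean lay above background, up to 4 members of each list with the largest absolute change, and the deleted genes. The fit was tested on simulated data for 5449 genes, 200 of them changed, in 20 simulations of 2 against 2 arrays. Gene means were the real ones. Variances were drawn from the fit's own prior, with normal noise and the same variance in both groups. It recovered 55.5% of changes of log2 0.5, 92.7% of changes of log2 1 and 98.8% of changes of log2 2, and 5.49% of its calls were false. Simulated lists of 25 genes shifted by log2 0.5 were called in 20 of 20 simulations in either direction, and an unshifted list in 0. The simulated genes varied independently of each other and no array-wide difference was simulated, so these rates do not cover correlated genes. Nor do they cover a spread that differs between groups. Differences of replicate arrays had an SD over genes of 0.121 for honokiol and 0.209 for ethanol. In the data the estimated correlation was 0.418 for ribosome biogenesis genes and 0.577 for trehalose and glycogen genes. The data also gave 2663 calls, against 200 changed genes per simulation.

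The alternatives were an intensity trend with a robust prior, quantile normalization again, centring of each array on its median, a filter on dim probe sets, all probe sets but AFFX controls as features (a gene then counted through its brightest probe set), the mean of a gene's probe sets, the replicate number as a block, and leaving out each array. After the data were seen, 2 more were added: a covariate for the 5'/3' signal ratio of control transcripts, and leaving out probe sets marked s or x. That ratio is the mean difference in log2 intensity between the 5' and the 3' probe set of 7 yeast control genes. The same was computed for 4 bacterial transcripts spiked into the RNA.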

Results

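The comparison asks which transcripts change when growing BY4741 yeast receives honokiol at 12 µg/mL for 2 h, against ethanol alone, with 2 arrays per group. The labels give a culture age of 8 h for all samples. Median log2 intensity over the 5449 tested genes was 9.57 and 9.59 on the honokiol arrays and 9.57 and 9.59 on the control arrays. Over genes, replicate arrays correlated at 0.998 for honokiol and 0.995 for ethanol, and arrays of different groups at 0.959 to 0.970. The values of replicate arrays were not copies: their differences had an SD over genes of 0.121 (honokiol) and 0.209 (ethanol) on the log2 scale.

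The largest rise was that of AZR1, a plasma membrane transporter linked to azole and acid resistance. Its log2 intensity was 10.18 ± 0.12 (SD, n = 2) with honokiol and 4.63 ± 0.16 (SD, n = 2) with ethanol, a 46.6-fold difference (log2 5.54 ± 0.11, SE; adjusted p = 0.000166) from a control level just above background. YGR035C, an uncharacterised gene, rose 12.3-fold (log2 3.62 ± 0.06, adjusted p = 0.000154) and HXT1, a low-affinity glucose transporter, 10.5-fold (log2 3.39 ± 0.12, adjusted p = 0.000669). The largest falls were those of ARO10 and ARO9, a decarboxylase and an aminotransferase of aromatic amino acid breakdown. ARO10 fell by 3.73 ± 0.06 and ARO9 fell by 2.77 ± 0.06 on the log2 scale (adjusted p = 0.000154 and 0.000248).

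Among the other large rises, CPA1, the small subunit of an arginine-pathway carbamoyl phosphate synthetase, rose 5.39-fold (adjusted p = 0.000825). YOR302W, the short reading frame in the CPA1 leader, rose 10.2-fold (adjusted p = 0.00137), and since both lie on the same transcript these are not independent measurements. PDH1, of propionate metabolism, rose 8.12-fold, CIS1 rose 7.69-fold and FIT2, a cell wall protein that retains siderophore iron, rose 5.18-fold (adjusted p = 0.00098, 0.000248 and 0.000265). The uncharacterised YGR079W rose 6.42-fold (adjusted p = 0.00098). YAR068W rose 6.01-fold and its neighbour YAR066W, whose probe set can bind several transcripts, 5.82-fold (adjusted p = 0.000384 and 0.00318). LSO1 was above background with honokiol only, so its rise was at least 1.65-fold (adjusted p = 0.000889).

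The other large falls had adjusted p between 0.000669 and 0.00206. WSC4, a membrane sensor-like protein, fell by 2.09 on the log2 scale, the oligopeptide transporter OPT2 fell by 2.08, the aldehyde dehydrogenase ALD3 fell by 2.02 and HMS1 fell by 1.92. The agglutinin anchor AGA1 fell by 1.85, the cell fusion gene FUS1 fell by 1.69 and the uracil permease FUR4 fell by 1.66. ISF1 fell by 1.50, INH1, which encodes an inhibitor of the mitochondrial ATP synthase, fell by 1.45, and HSP31 fell by 1.44. All 24 of these largest changes kept their direction and their call without each array in turn.

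**Figure D1:**
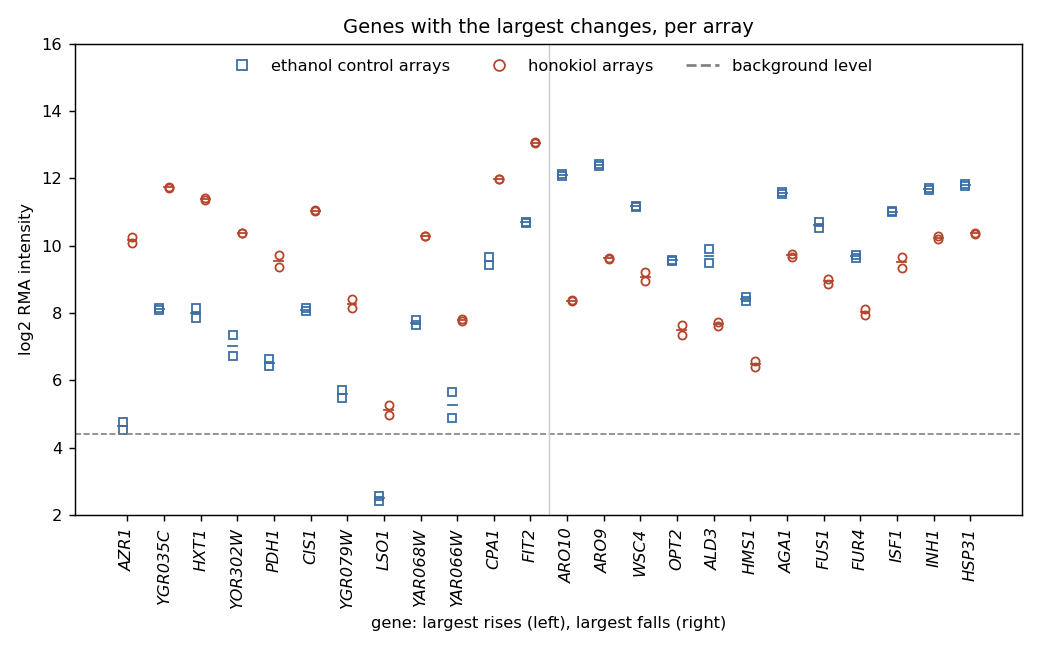
Log2 RMA intensity (vertical axis) of the 12 genes with the largest rises and the 12 with the largest falls (horizontal axis); squares are the 2 ethanol control arrays, circles the 2 honokiol arrays, short bars the group means and the dashed line the background level of 4.39. In all 24 genes both honokiol arrays lie on the same side of both control arrays, which was a condition for naming them. The control arrays of LSO1 lie below background, so its rank among the rises is uncertain.

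Across the genome, 2663 of 5449 genes passed the threshold, 1302 higher and 1361 lower with honokiol. At least 2-fold changes were rarer and mostly rises, with 206 genes higher and 52 lower. The 2663 genes all had both honokiol arrays on the same side of both controls, as did 80.2% of tested genes where chance gives 33.3%. Any difference between the groups of arrays raises this share, and the 5'/3' ratio of control transcripts was lower on both controls. Without honokiol 1 or honokiol 2 the number of genes past the threshold was 708 (439 higher, 269 lower) or 705 (441 higher, 264 lower), with rises then the majority and the spread then coming from the control pair alone. Of the 36 gene lists, 9 passed the list test as higher and 5 as lower, and 0 did with an estimated correlation, at which 3 lists reached an unadjusted p under 0.05. By fry, 15 lists were higher and 11 lower, all 14 lists above among them in the same direction. With all probe sets but AFFX controls as features, 14 lists were higher and 7 lower. Counts of genes adjusted over the list alone are given where they differ, as they do for 12 lists.

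Targets of Pdr1 and Pdr3 rose with honokiol. In the list for Pdr1 and Pdr3, transcription factors that control multidrug resistance, 12 of 16 genes rose and 1 fell (mean log2 fold change 1.12, SD over genes 0.94; adjusted p = 1.65e-06, and adjusted p = 0.376 with an estimated correlation). Besides YGR035C, RSB1, a membrane protein for release of sphingoid bases, rose 4.14-fold, the lysophosphatidic acid acyltransferase ICT1 3.79-fold and the phosphatidylinositol transfer protein PDR16 3.20-fold (adjusted p = 0.000349, 0.000625 and 0.000889). Of 24 genes in the Yap1 oxidative stress list, 8 rose and 2 fell (1 fell when adjusted over the list alone), and the list did not pass (mean 0.21, adjusted p = 0.0648). It passed with all probe sets as features, by fry and with the 5'/3' ratio of control transcripts as a covariate (adjusted p = 0.00139, 0.00804 and 0.0484). Its largest rises were those of the glutathione peroxidase GPX2 (2.37-fold, adjusted p = 0.00131) and the drug transporter ATR1 (1.85-fold, adjusted p = 0.00256).

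Genes of the iron and zinc regulons rose. Of 26 genes in the iron regulon 23 rose and 0 fell, or 23 and 1 when adjusted over the list alone (mean 1.05, SD 0.66; adjusted p = 3.25e-10, and adjusted p = 0.376 with an estimated correlation). Next to FIT2, the siderophore transporters SIT1 and ARN2 rose 4.60-fold and 3.58-fold (adjusted p = 0.000397 and 0.000669). TIS11, an mRNA-binding protein of the response to iron scarcity, rose 3.50-fold (adjusted p = 0.00316). In the zinc regulon 6 of 9 genes rose and 0 fell (mean 0.50, SD 0.42; adjusted p = 0.0149, and adjusted p = 0.474 with an estimated correlation). The zinc transporter ZRT1 rose 2.44-fold and IZH1 1.80-fold (adjusted p = 0.00131 and 0.00464). Of 8 copper homeostasis genes 4 rose and 0 fell, with the list not passing (mean 0.35, adjusted p = 0.0639; 0.00798 with all probe sets as features and 0.0254 by fry); the copper transporter CTR1 rose 1.93-fold (adjusted p = 0.00233). The zinc genes were on average 0.15 higher (log2) on ethanol control 1 than on ethanol control 2.

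The lists for phosphate and for sulfate and methionine were also higher. In the phosphate regulon 7 of 16 genes rose and 1 fell (mean 0.49, SD 0.72; adjusted p = 0.0427, and adjusted p = 0.474 with an estimated correlation). The list did not pass without ethanol control 1 (adjusted p = 0.0713) or without probe sets that can share targets (adjusted p = 0.0828). The phosphate transporter PHO89 rose 3.39-fold, PHM6 3.52-fold, the phosphatase PHM8 2.35-fold and PHO11, an acid phosphatase with close paralogs, 2.93-fold (adjusted p = 0.00137, 0.00328, 0.00142 and 0.00128). In the list for sulfate assimilation and methionine 18 of 23 genes rose and 0 fell (mean 0.72, SD 0.52; adjusted p = 1.05e-07, and adjusted p = 0.376 with an estimated correlation). MET2, which encodes homoserine acetyltransferase, rose 4.28-fold (log2 2.10 ± 0.06, adjusted p = 0.000349). The S-methylmethionine permease MMP1, the cystathionine beta-lyase STR3 and the methionine permease MUP3 rose 2.49-fold, 2.38-fold and 2.33-fold (adjusted p = 0.00319, 0.00351 and 0.00131).

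Gcn4-controlled amino acid genes went both ways: 12 of 31 rose and 8 fell, or 13 and 8 when adjusted over the list alone, and the list did not pass (mean 0.25, adjusted p = 0.224; 0.0455 with all probe sets as features and 0.0173 by fry). After CPA1, the rises were largest for LYS20, the homocitrate synthase of lysine synthesis (3.80-fold, adjusted p = 0.000491), ILV5 of branched-chain synthesis (2.68-fold, adjusted p = 0.00545) and ARG1, argininosuccinate synthetase (2.25-fold, adjusted p = 0.00163). In the thiamine and vitamin B6 list 7 of 14 genes rose and 2 fell, with the list not passing (mean 0.24, adjusted p = 0.182; 0.037 with all probe sets as features and 0.0346 by fry); THI4 rose 2.08-fold and SNZ1 1.91-fold (adjusted p = 0.00306 and 0.00183).

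Genes for making ribosomes rose together. Of 93 ribosome biogenesis genes 81 rose and 0 fell, or 83 and 0 when adjusted over the list alone (mean 0.69, SD 0.40; adjusted p = 3.05e-19, and adjusted p = 0.474 with an estimated correlation). All 93 fold changes were positive. UTP23 and NSR1, both of pre-ribosomal RNA processing, rose 4.44-fold each (log2 2.15 ± 0.13 and 2.15 ± 0.14, adjusted p = 0.00131 and 0.00139), NOP15 rose 2.66-fold and RLP24 2.62-fold (adjusted p = 0.00244 and 0.00414). These genes were on average 0.13 higher (log2) on ethanol control 1 than on ethanol control 2. Of 129 cytosolic ribosomal protein genes 46 rose and 0 fell, or 38 and 0 when adjusted over the list alone (mean 0.22, SD 0.25; adjusted p = 5.63e-08, and adjusted p = 0.474 with an estimated correlation). RPS9A rose 3.33-fold and RPL22B 2.54-fold (adjusted p = 0.000846 and 0.00175). Many of these genes are near-identical pairs, and 22 of the 129 probe sets can bind several transcripts. The list's median log2 fold change was 0.144, close to the median of 0.136 over the 1366 tested genes with the shortest coding sequences. With the 5'/3' ratio as a covariate, the list's mean was 0.20 and the median of those short genes 0.06. Camera compared the list with genes of all lengths, so whether the list rose beyond other genes of its length was not tested. Of 66 genes for the mitochondrial ribosome 16 rose and 7 fell, or 9 and 4 when adjusted over the list alone, and the list did not pass (mean 0.05, from 0.03 to 0.08 over the alternatives; adjusted p = 0.245); MRPL17 fell by 0.59 on the log2 scale (adjusted p = 0.00346).

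Histone genes and genes of the G1/S transition were higher. Of 9 histone genes 6 rose and 0 fell (mean 0.45, SD 0.34; adjusted p = 0.00411, and adjusted p = 0.474 with an estimated correlation), with HTA1 up 1.91-fold and HHT1 1.71-fold (adjusted p = 0.00131 and 0.00208). Paralogous histone genes share most of their sequence. Of 14 G1/S genes 8 rose and 0 fell (mean 0.34, SD 0.34; adjusted p = 0.022, and adjusted p = 0.474 with an estimated correlation). G1/S genes were on average 0.10 higher (log2) on ethanol control 1 than on ethanol control 2. With the 5'/3' ratio as a covariate their mean was 0.25, and the list still passed at the preset correlation (adjusted p = 0.0307). The ribonucleotide reductase subunit RNR1 rose 2.09-fold (adjusted p = 0.00263). The cyclin CLN2 rose 1.46-fold (adjusted p = 0.00647) but did not pass without honokiol 1 or honokiol 2 (adjusted p = 0.0662 and 0.0561). In the list for G2/M and M/G1, 4 of 16 genes rose and 3 fell, and the list did not pass (mean 0.06, from 0.00 to 0.10 over the alternatives; adjusted p = 0.595): the daughter-cell wall gene SCW11 rose 1.92-fold and the mitotic cyclin CLB1 fell by 0.92 on the log2 scale (adjusted p = 0.00212 and 0.00171). In the DNA damage list 3 of 11 genes rose and 1 fell (mean 0.23, adjusted p = 0.218; 0.0242 by fry), with HUG1 up 2.75-fold (adjusted p = 0.00219).

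**Figure D2:**
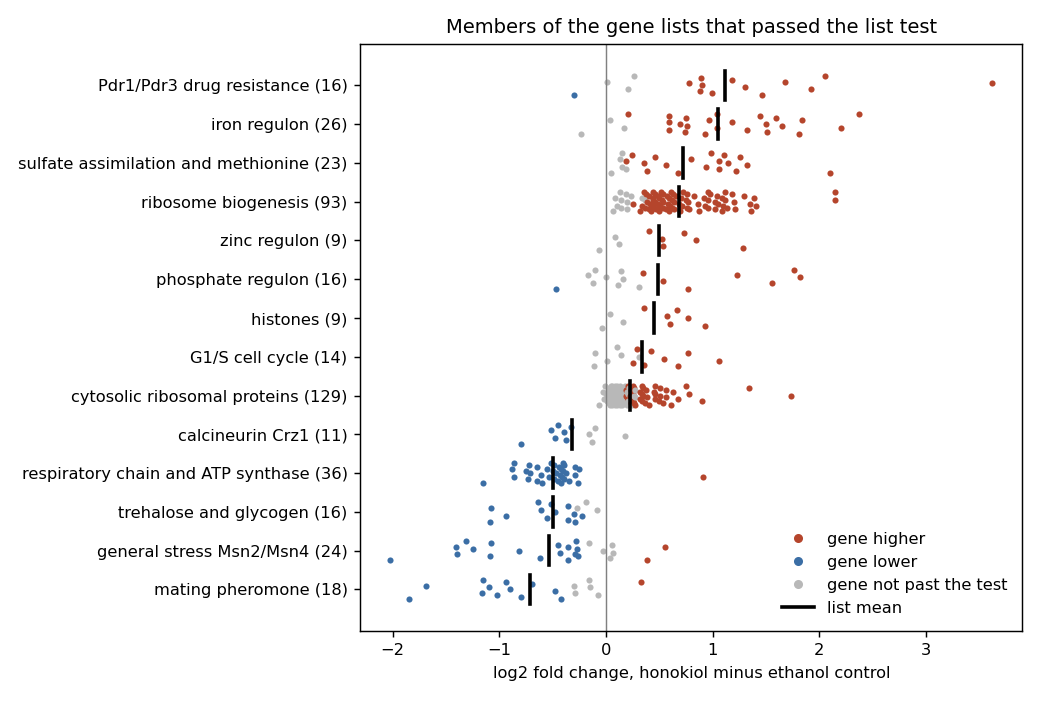
Log2 fold change, honokiol minus ethanol control (horizontal axis), of each measured member of the 14 gene lists that passed the list test, with the number of members in parentheses. Red points are genes that rose, blue points genes that fell, grey points genes not past the test, and black bars list means, which run from -0.71 for mating pheromone genes to 1.12 for drug resistance genes.

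Respiratory genes fell. In the list for the respiratory chain and ATP synthase 35 of 36 genes fell and 1 rose (mean -0.49, SD 0.31; adjusted p = 3.36e-10, and adjusted p = 0.474 with an estimated correlation). COR1, a subunit of the cytochrome bc1 complex, fell by 0.88 and COX4, a subunit of cytochrome c oxidase, fell by 0.86 on the log2 scale (adjusted p = 0.00189 and 0.00175). The external NADH dehydrogenases went apart: NDE2 fell by 1.15 (adjusted p = 0.00268), while NDE1 was the gene that rose, 1.88-fold (adjusted p = 0.00147). Of 11 TCA cycle genes 6 fell and 2 rose, or 6 and 3 when adjusted over the list alone, and the list did not pass (mean -0.17, adjusted p = 0.224; 0.0254 by fry). The 2-oxoglutarate dehydrogenase subunits KGD2 and KGD1 fell by 0.83 and 0.72 (adjusted p = 0.00343 and 0.00212), and IDH1, a subunit of isocitrate dehydrogenase, rose 2.06-fold (adjusted p = 0.00189).

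Of 12 hexose transporter and sensor genes 4 rose and 5 fell; the mean was 0.41 and the median -0.06, differing in sign, and the list did not pass (adjusted p = 0.792; 0.0256 by fry). Besides HXT1, HXT2 rose 3.52-fold and HXT3 2.23-fold, while HXT7, whose probe set cannot be told from its near-identical neighbour HXT6, fell by 0.72 on the log2 scale (adjusted p = 0.000672, 0.00103 and 0.00377). In glycolysis 0 of 15 genes passed the limma test (mean 0.02, from -0.02 to 0.03 over the alternatives, SD 0.08; list adjusted p = 0.705), and PFK1 had the largest absolute change, log2 -0.17 ± 0.07 (adjusted p = 0.0906; 0.0117 with an intensity trend and robust prior and 0.0438 without ethanol control 1). With that trend and prior HXK2, PFK2 and PGK1 also passed (adjusted p = 0.00751, 0.0335 and 0.0161), so the 0 depends on the setting. In the gluconeogenesis and glyoxylate list 4 of 13 genes rose and 2 fell (mean 0.31, from 0.16 to 0.43 over the alternatives; adjusted p = 0.224), and the list passed without honokiol 2 (adjusted p = 0.0453). The peroxisomal citrate synthase CIT2 rose 2.80-fold and the gluconeogenic PCK1 2.44-fold (adjusted p = 0.000818 and 0.00256). For beta-oxidation 5 of 14 genes fell and 2 rose (mean -0.11, from -0.22 to -0.05 over the alternatives; adjusted p = 0.226), with POT1 down by log2 fold change -1.19 (adjusted p = 0.00223).

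General stress genes and trehalose and glycogen genes fell. Of 24 genes in the general stress list for Msn2 and Msn4, 17 fell and 2 rose, or 18 and 2 when adjusted over the list alone (mean -0.53, SD 0.64; adjusted p = 0.000223, and adjusted p = 0.474 with an estimated correlation). After ALD3, RTN2 fell by 1.41, the catalase CTT1 fell by 1.40 and MSC1 fell by 1.31 on the log2 scale (adjusted p = 0.000889, 0.00241 and 0.00179). In the trehalose and glycogen list 13 of 16 genes fell and 0 rose, or 15 and 0 when adjusted over the list alone (mean -0.50, SD 0.31; adjusted p = 8.34e-05, and adjusted p = 0.474 with an estimated correlation). GDB1 and GPH1, which break down glycogen, fell by 1.09 and 1.08 (adjusted p = 0.00377 and 0.00417). On ethanol control 1 these lists lay on average below ethanol control 2, with a mean difference of -0.09 for general stress and -0.17 for trehalose and glycogen, as did the heat shock list at -0.09. Of 24 heat shock chaperone genes 7 fell and 1 rose, or 6 and 1 when adjusted over the list alone, and the list did not pass (mean -0.14, from -0.18 to -0.06 over the alternatives; adjusted p = 0.181); SSA4 fell by 1.15 and HSP26 fell by 0.57 (adjusted p = 0.00189 and 0.00316). Of 8 genes of the weak acid response 2 fell and 0 rose (mean -0.20, adjusted p = 0.308; 0.0149 by fry), the larger fall being that of the acid efflux pump PDR12, which fell by 1.33 (adjusted p = 0.0013).

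Protein quality control lists did not pass with camera at the preset correlation. In the unfolded protein response 7 of 16 genes fell and 1 rose, or 8 and 1 when adjusted over the list alone (mean -0.14, adjusted p = 0.144; 0.00344 by fry), and EUG1 and SIL1 fell by 0.87 and 0.64 on the log2 scale (adjusted p = 0.00286 and 0.00262). Of 33 proteasome genes 5 rose and 0 fell, or 3 and 0 when adjusted over the list alone (mean 0.08, from 0.06 to 0.13 over the alternatives; adjusted p = 0.308); RPN4, the transcription factor of proteasome genes, rose 2.14-fold and PUP3 1.60-fold (adjusted p = 0.00131 and 0.00212). The proteasome list passed with quantile normalization again (adjusted p = 0.0398). Of 34 autophagy genes 6 rose and 15 fell (mean -0.06, from -0.11 to -0.03 over the alternatives; adjusted p = 0.224 and 0.0362 by fry), with ATG40 up 2.19-fold and ATG34 down by log2 fold change -0.81 (adjusted p = 0.00103 and 0.00189). For the vacuolar ATPase 4 of 14 genes fell and 0 rose (mean -0.15, adjusted p = 0.0516; 0.018 with an intensity trend and robust prior, 0.0361 with all probe sets as features and 0.00413 by fry). VMA13 had the largest absolute change, log2 -0.36 (adjusted p = 0.0226; 0.147 without honokiol 1 and 0.107 without honokiol 2).

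Mating genes fell. Of 18 mating pheromone genes 12 fell and 1 rose (mean -0.71, SD 0.57; adjusted p = 1.03e-05, and adjusted p = 0.474 with an estimated correlation). After AGA1 and FUS1, the agglutinin subunit AGA2 and the pheromone protease BAR1 fell by 1.17 and 1.15 on the log2 scale (adjusted p = 0.00256 and 0.00132). Of 11 calcineurin and Crz1 target genes 7 fell and 0 rose (mean -0.32, SD 0.26; adjusted p = 0.017, and adjusted p = 0.474 with an estimated correlation), RCN1, a calcineurin regulator, having the largest fall at log2 fold change -0.80 (adjusted p = 0.00183). In the cell wall integrity list 6 of 20 genes rose and 4 fell, and the list did not pass (mean 0.09, from 0.02 to 0.13 over the alternatives; adjusted p = 0.308). GSC2, a glucan synthase subunit, fell by 0.89 and the kinase-like gene KDX1 rose 1.82-fold (adjusted p = 0.00158 and 0.00253).

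Membrane lipid genes went both ways. Of 26 ergosterol genes 5 rose and 6 fell (mean 0.00, from -0.01 to 0.03 over the alternatives; adjusted p = 0.967): the desaturase ERG3 rose 2.20-fold and HMG2 fell by 0.93 on the log2 scale (adjusted p = 0.00208 and 0.0048). In the fatty acid and phospholipid list 4 of 18 genes rose and 9 fell (mean -0.17, adjusted p = 0.0598; 0.0291 with an intensity trend and robust prior, 0.0396 with all probe sets as features and 0.00344 by fry). The fatty acid desaturase OLE1 rose 2.22-fold and FAA4 2.22-fold, while the choline kinase CKI1 and the methyltransferase OPI3 fell by 1.06 and 0.78 (adjusted p = 0.00472, 0.00117, 0.00117 and 0.0019). Of 15 hypoxic and anaerobic genes 8 rose and 2 fell (mean 0.40, from 0.24 to 0.49 over the alternatives; adjusted p = 0.0648). That list passed without honokiol 2, ethanol control 1 or ethanol control 2 (adjusted p = 0.0426, 0.0447 and 0.0463) and with quantile normalization again or with all probe sets as features (adjusted p = 0.042 and 0.00856). It did not pass with the 5'/3' ratio as a covariate, where its mean was 0.24 (adjusted p = 0.0817), or without probe sets that can share targets (adjusted p = 0.133). Its genes were on average 0.19 higher (log2) on ethanol control 1 than on ethanol control 2. ANB1 rose 1.92-fold (adjusted p = 0.00213), and PAU24, whose probe set can bind other members of its family, 2.28-fold (adjusted p = 0.00346).

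**Figure D3:**
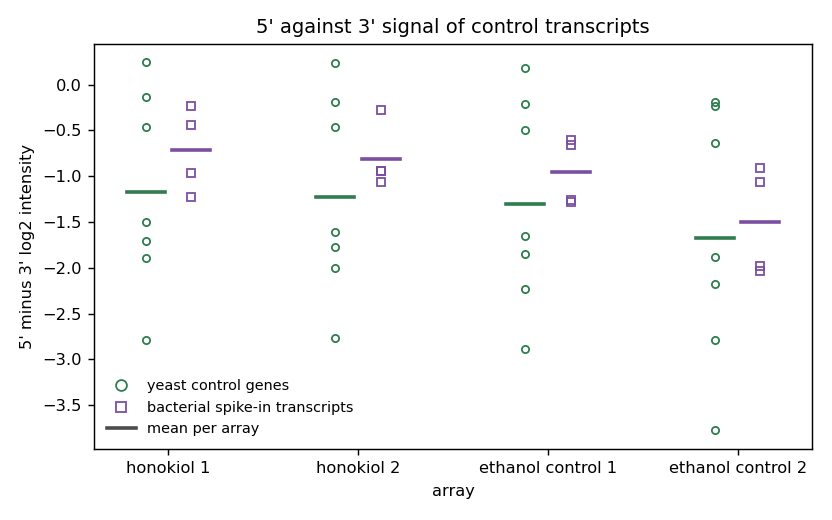
Difference in log2 intensity between the 5' and the 3' probe set (vertical axis) of 7 yeast control genes (circles) and 4 bacterial spike-in transcripts (squares) on each array (horizontal axis), with bars for the mean per array. The mean is lowest on ethanol control 2 for both kinds, -1.67 and -1.50.

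The arrays differed in the 5' signal of control transcripts. The mean 5' minus 3' difference over the yeast control genes was -1.18 and -1.22 on the honokiol arrays and -1.31 and -1.67 on the control arrays. Over the spike-in transcripts it was -0.71 and -0.81 with honokiol and -0.95 and -1.50 with ethanol. With this ratio as a covariate, added after the data were seen, 1867 genes passed, and 1730 of these were among the 2663 and had the same direction.

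Of the genes deleted in BY4741, URA3 had log2 intensity 2.92 ± 0.26 (SD, n = 2) with honokiol and 2.74 ± 0.02 (SD, n = 2) with ethanol, under background in both groups. LEU2 (4.38 and 4.41) and MET17 (4.52 and 4.49) lay at the background level. HIS3, of which the strain keeps a part, was at 10.72 and 11.05. As its probe set was not placed within the gene, that level says nothing about the label.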

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

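Of 3470 probe sets with no gene name here that are not controls, 26 were higher and 81 lower with honokiol when all probe sets but AFFX controls were tested together. Of these, 3 were higher by at least 2-fold, by log2 1.49, 1.43 and 1.22 (adjusted p = 0.00385, 0.00385 and 0.00532). They stand here because a signal above the controls appeared in data that the gene comparison does not use. All 3 were bright, at log2 intensity 8.68 to 12.73 with honokiol and 7.43 to 11.32 with ethanol, and the arrays of the groups did not overlap. Another 2 were lower by at least 2-fold, with log2 fold changes of -1.57 and -1.22 (adjusted p = 0.00447 and 0.00532). Of the 1747 probe sets for genes of another species, 2 were higher, 26 were lower and 0 reached 2-fold, by limma. With 2 arrays per group, no test for single outlying arrays was run.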

How the results depend on the processing

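The 5'/3' covariate and leaving out probe sets marked s or x were chosen after the data were seen. Over 13 alternatives for genes and 15 for lists, 0 called values changed sign, and all 24 genes of largest change kept their call wherever they were tested. LSO1 and YAR066W have a value in 12 of the 13, as LSO1 is removed as dim and YAR066W as shared. Of the 175 named genes past the threshold, 12 are removed as dim or shared in some alternative. Of the 163 tested in all, 111 passed in all; of the 12, 9 passed wherever tested. The other 55 did not pass without honokiol 1 or honokiol 2, among which 2 did not without an ethanol array and 15 with the covariate. Leaving out an array gave 705 to 3190 genes changed, 439 to 1634 higher and 264 to 1556 lower. The lowest values came without a honokiol array: the lone array is assumed to vary like the control pair, which had the wider spread (SD of differences 0.209 against 0.121). With all probe sets as features, 1763 probe sets changed; counted as genes, each through its brightest probe set, 1611 changed, 832 higher and 779 lower. In that setting 14 lists were higher, compared with a set that also held the 1747 probe sets of another species and the 3470 without a gene name. Of the latter, 409 had a mean above background. The causes of the larger number of lists were not tested. An estimated correlation left 0 lists higher and 0 lower, and it alters both the correlation and the degrees of freedom of the test. For the Pdr1/Pdr3, sulfate and methionine, and calcineurin lists the estimated correlation was below the preset 0.01 (-0.054, -0.037 and -0.055). A higher correlation therefore cannot be why these lists no longer passed. For the other called lists the correlation and the degrees of freedom were not separated. By fry, which does not compare a list with other genes, 15 were higher and 11 lower. All other counts stayed within 1.5 times. The replicate numbers name no shared culture or day, and the difference of replicate 1 from 2 correlated at 0.325 between the groups over genes. With the replicate number as a block, 2809 genes changed, 1414 higher and 1395 lower, and the lists were the same in number, 9 and 5. Of the tested genes, 29 were under background in both groups, where a change cannot be seen.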

Other observations

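Gene groups picked after their values were seen showed further changes, tested with camera and adjusted over 6 such lists, so they are no independent evidence. Of 15 amino acid permease genes 8 rose and 2 fell (mean log2 fold change 0.33, adjusted p = 0.0293, and adjusted p = 0.45 with an estimated correlation). DIP5, for glutamate and aspartate, rose 3.08-fold and TAT1 2.32-fold, while the general permease GAP1 fell by 1.29 on the log2 scale. In aromatic amino acid breakdown 4 of 6 genes fell and 1 rose (mean -1.20, adjusted p = 0.0293, and adjusted p = 0.396 with an estimated correlation). Besides ARO10 and ARO9, the activator ARO80 fell by 0.62, a call lost without honokiol 1 or honokiol 2 (adjusted p = 0.12 and 0.0902). Of 7 genes for NAD synthesis from tryptophan 5 fell and 0 rose (mean -0.44, adjusted p = 0.00676, and adjusted p = 0.396 with an estimated correlation), BNA1 with log2 fold change -0.95.

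Of 12 RNA polymerase III subunits 10 rose and 0 fell (mean 0.46, adjusted p = 0.000526, and adjusted p = 0.396 with an estimated correlation). The calls of RPC17, RPC25 and RPC31, which rose 1.60-fold, 1.59-fold and 1.54-fold, were lost without honokiol 1 (adjusted p = 0.0879, 0.0926 and 0.0518) or honokiol 2 (adjusted p = 0.0856, 0.0661 and 0.0657). Of 13 seripauperin genes 11 rose and 0 fell (mean 0.55, adjusted p = 0.000526, and adjusted p = 0.443 with an estimated correlation), but 11 of their probe sets can bind several family members. In pyrimidine uptake and synthesis 4 of 14 genes rose and 6 fell (mean -0.23, adjusted p = 0.0969). The permeases FUR4 and FUI1 fell by 1.66 and 1.20 on the log2 scale. The CTP synthases moved apart: URA8 fell by 1.30 and URA7 rose 2.09-fold, a call lost without honokiol 2 (adjusted p = 0.0502).

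Of the tests below, the one that leaves out the genes of the fixed lists was chosen before its result was seen and the others after. Ribosome biogenesis genes were higher with honokiol, and control 2 had the lowest 5' signal and the lower level of these genes among the controls. Differences in labelling of the transcripts' 5' part were examined as the whole cause, with the 5'/3' ratio as a covariate. In that fit, with 1 fewer residual degree of freedom, the mean log2 fold change was 0.60 (SE over genes 0.036). The list passed at the preset correlation (adjusted p = 5.98e-20). A labelling effect linear in this ratio, as fitted, did not account for the whole rise. Labelling is not excluded, because the ratio is lower on both control arrays and its slope rests mainly on that pair. The SE treats genes as independent, though their estimated correlation was 0.418 in the main fit. Without the covariate the list did not pass at an estimated correlation (adjusted p = 0.474), which was not run with the covariate. Control cultures nearer to the end of their glucose could also give higher ribosome biogenesis and lower storage and respiratory genes with honokiol. Genes that glucose represses should then be lower with honokiol, and the gluconeogenesis and glyoxylate list had a mean of 0.31 (SE over genes 0.18) with members going both ways, 0.16 with the 5'/3' covariate, and array differences within groups of 0.17 (ethanol) and 0.23 (honokiol), so this stays open, as does an effect of honokiol itself, since growth was not measured here.

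Respiratory genes were lower while the iron regulon was higher. A loss limited to transcripts of iron-containing proteins is argued against: the 11 ATP synthase subunits in the list, which hold no iron, all fell. Their mean log2 fold change was -0.41 (SE over genes 0.030). The other 25 members, which were not split by iron content and include NDE1, which rose, had a mean of -0.53 (SE 0.073). These SEs treat genes as independent. With the 5'/3' ratio as a covariate the list's mean was -0.55 (SE over genes 0.051, adjusted p = 3.92e-11 at the preset correlation). A labelling effect linear in this ratio, as fitted, thus did not account for the fall. Labelling is not excluded, as the ratio differs between the groups. The estimated correlation of these genes was 0.296 in the main fit, so the SE is too small. Without the covariate the list did not pass at an estimated correlation (adjusted p = 0.474). A fall of respiratory transcripts as a whole, by honokiol or by a difference in growth, may remain and was not tested further.

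Shorter genes tended to be higher with honokiol: over genes, which are not independent replicates, Spearman's rho of log2 fold change with coding length was -0.29. The fixed lists do not account for it, as rho was -0.32 over the 4562 genes outside them. Labelling may account for part: rho was -0.15 with the 5'/3' ratio as a covariate and -0.21 without ethanol control 2. Array pairs of the same group showed such a trend too, with rho -0.25 for honokiol 1 minus honokiol 2 and -0.44 for ethanol control 1 minus ethanol control 2. Whether labelling is the whole cause stays open, because the ratio is lower on both control arrays than on both honokiol arrays.

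The spike-in transcripts had a mean log2 intensity of 7.06 and 6.46 on the honokiol arrays and 7.57 and 7.42 on the control arrays.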
